A study of Arabidopsis thaliana with 14 samples.

How the data were processed

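Transcript levels were measured with Affymetrix arrays in Arabidopsis thaliana plants of the wild-type accession Col-7 and of gir1, a mutant named for glucose-inhibited root elongation. Roots came from plants aged 21 days (3 gir and 3 Col-7 arrays). Inflorescences came from soil-grown plants aged 33 days (4 gir and 4 Col-7 arrays). RNA was extracted with a column kit for plant tissue, per the labels' protocols. The deposited values are intensities on a linear scale, computed with MAS5 per the submitters' processing notes, 1 value for each of 22810 probe sets and no detection calls. The MAS5 version and the genome build were not given in the sources used here. In each array the mean of the deposited intensities without the lowest and highest 2% was 500, which is how the arrays had been scaled to one another. Arrays carry no read depth, so their number limits the precision. The labels do not say that replicates came from separate cultures or plants, so p-values measure the spread between these samples, part of which may be technical.

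Samples were grouped by the tissue and genotype in their titles. Intensities were taken as log2(intensity + 26), where 26 is the 20th percentile of all values. Fold changes are on that scale, which understates the change of dim probe sets. The 64 control probe sets were left out. A probe set was tested in a tissue where it reached the array's own 40th percentile on at least as many arrays as the smaller group held. Each tissue was fitted separately with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The difference of the genotype effect between tissues was the interaction term of a fit over all 14 arrays, for probe sets tested in both tissues. Overlaps of calls were tested with Fisher's exact test, two-sided. The root and inflorescence comparisons share no arrays. The plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

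On simulated data with the spread of the real arrays, the root fit over 13799 probe sets recovered 58% of changes of 0.5 on the log2 scale, 94% of changes of 1 and 100% of changes of 2. The inflorescence fit over 13970 probe sets recovered 58%, 88% and 98% of the same sizes. The interaction fit over 11911 probe sets was tried on data simulated with the same spread for every probe set, not that of the real arrays. There it recovered 91.5% of changes of 1. Unchanged probe sets were called 5, 12 and 16 times in the 3 simulations.

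Genes were named from the platform annotation given for the probe sets, updated through gene identifiers to the symbols of the TAIR10.1 gene table. Of 14016 listed probe sets, 13513 named 1 gene and 503 named several. 13436 of the former matched the gene table and stood for 13286 genes. Another 8730 probe sets are unnamed here. Only probe sets naming 1 gene are reported by gene, and a gene without a symbol is given by its locus. No given table tied GIR1 of this study to a locus or probe set, so the level of the mutated gene was not analysed here.

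Before the data were examined, 28 gene lists with 527 loci were fixed, together with the tests, the alternatives and the rule for named genes. Only 70 of those loci had a probe set naming that gene alone, 37 of them tested in roots and 42 in inflorescences, and most lists were therefore too small for a list test. Lists with 5 or more tested genes were tested with limma's camera at a preset correlation of 0.01, with 1 probe set per gene, the one of highest mean. The named genes were, per tissue, the 12 with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap. Added to them were up to 4 past the threshold from each list, the 3 of smallest p from a list past its test, up to 10 past the threshold in both tissues in the same direction, and the 5 of smallest p in the interaction. Families named by a shared symbol stem (24) were added after the data had been seen, as was the choice to leave out inflorescence replicates 3 and 4 of both genotypes.

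The labels number the replicates of both genotypes alike. Whether the numbers pair the samples was checked from the data by correlating deviations from the group means. In inflorescences the same-numbered arrays correlated at 0.587, 0.191, 0.203 and 0.516, so, with all above 0.1, the numbers were taken to pair those arrays. The match is not exact, since gir replicate 3 correlated more with Col-7 replicate 4 (0.249), and Col-7 replicate 3 more with gir replicate 4 (0.402). Above 0.1 too were gir replicate 1 with Col-7 replicate 2 (0.188) and gir replicate 2 with Col-7 replicate 1 (0.119). The correlations therefore do not tell pairs by number from 2 batches, replicates 1 and 2 against replicates 3 and 4. In roots same-numbered arrays correlated at 0.077, 0.007 and 0.017 and were not taken as pairs. The main inflorescence fit left the pairing out, which entered the fits only as a block among the alternatives. No pair of arrays shared more than 2 identical values, so every array counts as 1 replicate. Alternatives covered other scalings (quantile normalization and median centring), pseudocounts of 6.5 and 104, no filter and a filter at the 60th percentile, eBayes with trend and robust settings, array weights, thresholds of 0.1 and of 2-fold, the replicate number as a block, a joint fit of all 14 arrays, an estimated correlation and fry for the list tests, and leaving out each array in turn.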

Results

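Expression in roots and inflorescences of gir1 plants was compared with that of wild-type Col-7, to describe how transcript levels differ between the lines in each tissue. Root plants had grown on plates without glucose for 11 days and then on 4% glucose for 10 days, per the series' design text. The sample protocol instead gives 7 days on a first plate without glucose and no time on the plates that followed, so the durations are uncertain. Opened and opening flowers had been removed from the inflorescences. Within a group, arrays correlated at 0.989 to 0.993 in roots and at 0.965 to 0.991 in inflorescences, while arrays of different genotypes correlated at 0.978 to 0.982 and at 0.882 to 0.927 respectively. Root hair and late pollen markers matched the tissue labels. The root hair expansins EXPA7 and EXPA18 averaged 9.95 ± 0.04 (log2 intensity, SD, n = 3) in Col-7 roots and 5.50 ± 0.20 (n = 4) in Col-7 inflorescences. The late pollen genes averaged 5.01 ± 0.10 (n = 3) and 8.55 ± 0.05 (n = 4) in the same samples. Differences were smaller for the floral identity list (5.67 in Col-7 roots and 6.38 in Col-7 inflorescences) and the meiosis list (5.70 and 5.94). Most members of both lists were dim, so the floor limits these differences. In Col-7 inflorescences UFO, CLV3, AGL24 and JAG had mean intensities of 3.4 to 71.4 and the meiosis genes 26.3 to 54.6. The 40th percentiles of those arrays were 132 to 140. SPT, the remaining floral gene, was at 176 in Col-7 roots and 461 in Col-7 inflorescences.

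In gir roots, genes for a cytochrome P450, isocitrate lyase and a MADS-box transcription factor were higher, and a polygalacturonase gene and an expansin gene were among the 12 largest falls of named genes. The P450 gene CYP718 (AT2G42850) rose from a mean intensity of 18.8 in Col-7 to 145 in gir (n = 3 each), a log2 change of 1.96 ± 0.19 (SE, adjusted p = 0.00087). ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle, rose from 245 ± 12.7 to 650 ± 32.0 (SD, log2 change 1.32 ± 0.07, adjusted p = 0.00017). AGL19 (AT4G22950), a MADS-box factor, rose from 95.9 ± 5.30 to 237 ± 15.4 (1.11 ± 0.08, adjusted p = 0.00026). The locus AT3G19430 showed the largest fall among named genes, from 311 ± 58.8 to 42.2 ± 10.3 (-2.30 ± 0.14, adjusted p = 0.00017). AT5G14650, which encodes a polygalacturonase, fell from 1127 ± 241 to 299 ± 55.0 (-1.82 ± 0.17, adjusted p = 0.00081). EXPA15 (AT2G03090), an expansin that loosens cell walls, fell from 3786 ± 248 to 1741 ± 30.7 (-1.11 ± 0.07, adjusted p = 0.00026). ATC (AT2G27550), a relative of TERMINAL FLOWER 1, fell from 2286 ± 262 to 975 ± 128 (-1.21 ± 0.12, adjusted p = 0.00085). In the gir samples for AT3G19430 and the Col-7 samples for CYP718 and AGL19, every array lay below its own 40th percentile. The floor therefore limits the size of these changes and their rank. The other 8 named loci among the largest falls lay between -1.37 and -0.99, and the other 9 among the largest rises between 1.07 and 1.46.

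**Figure D1:**
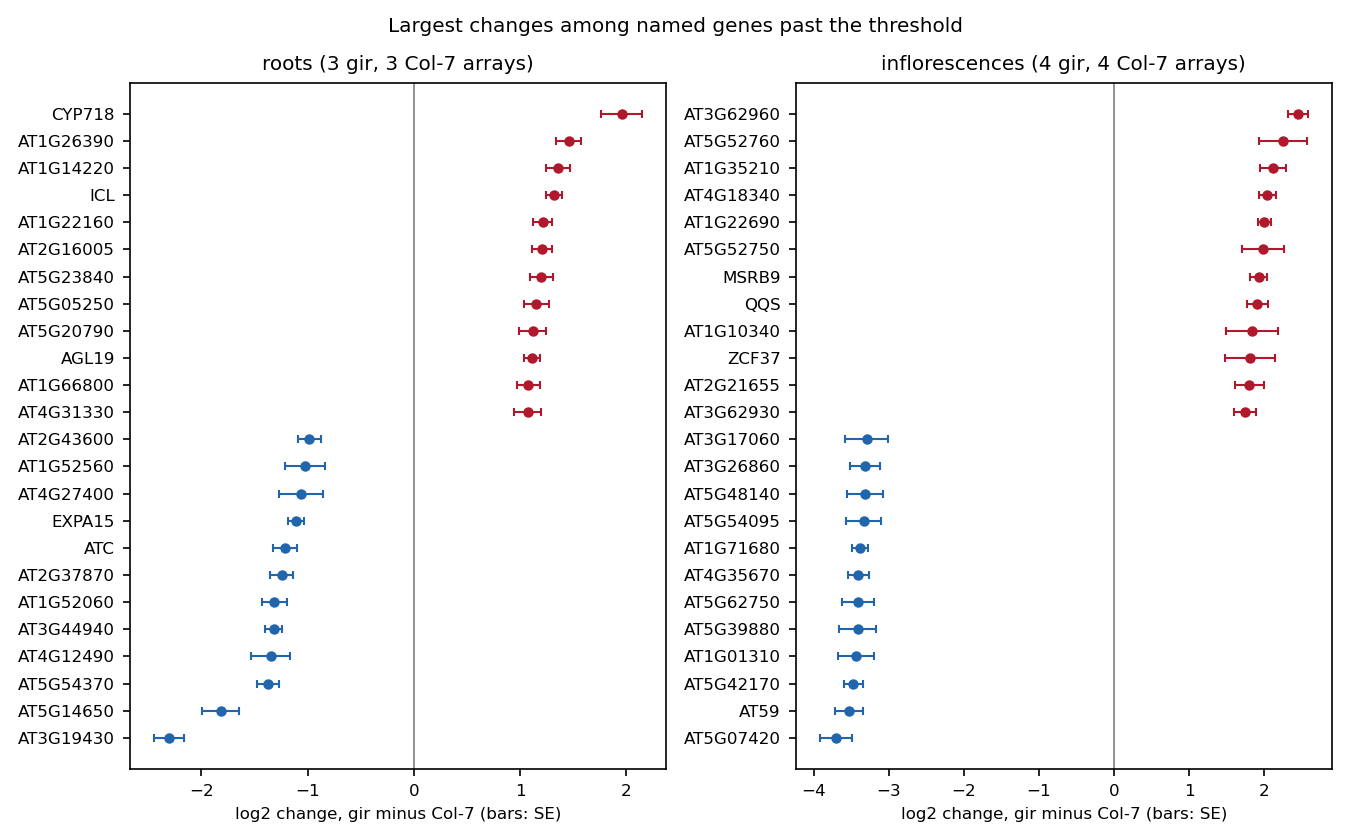
Log2 change of gir over Col-7 (x axis, log2 of intensity plus 26) for the 12 largest rises and the 12 largest falls of named genes past the threshold with groups that did not overlap, in roots (left) and inflorescences (right). Points are estimates and bars their SE; the root falls end at -2.30 (AT3G19430) and all 12 inflorescence falls lie between -3.71 and -3.29.

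Of 13799 probe sets tested in roots, 1636 passed the threshold, 758 higher and 878 lower in gir, and 28 of the former and 22 of the latter changed at least 2-fold. The count was 616 without the filter on dim probe sets and 707 in a joint fit with the inflorescence arrays, and it fell to 863, 814 and 1038 without gir replicate 1, gir replicate 2 and Col-7 replicate 2. Median centring moved the balance to 1037 higher and 690 lower. The ratio of 3' to 5' actin control signal was 1.67 ± 0.06 in gir roots and 1.49 ± 0.08 in Col-7 roots (SD, n = 3), that of GAPDH 0.943 ± 0.042 and 0.888 ± 0.0361, and the 25S ribosomal RNA control signal lay at 390 to 774 in gir roots and at 865 to 1270 in Col-7 roots.

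Among the fixed lists, the 5 measured genes of flavonoid and anthocyanin synthesis gave 1 fall past the threshold in gir roots, and 3 adjusted over the list alone. DFR (AT5G42800), the dihydroflavonol reductase, fell from 3635 ± 242 to 2682 ± 79.1 (-0.43 ± 0.08, adjusted p = 0.0086). UF3GT, a glycosyltransferase of anthocyanins, was at -0.23 ± 0.07 (adjusted p = 0.057) and AT4G14090 at -0.39 ± 0.12 (adjusted p = 0.073), while UGT78D2 (-0.05 ± 0.07) and AT5MAT (-0.08 ± 0.12) passed neither adjustment. The list as a whole passed camera (p = 0.012), but not with an estimated correlation (p = 0.22). No other fixed list was large enough in roots, so adjustment left both p-values unchanged, and the families added later were adjusted apart. The list also failed without the filter (adjusted p = 0.085) and without Col-7 replicate 1 (adjusted p = 0.071), and its alternatives ranged from 0.0033 to 0.22. EXPA7, expressed in root hairs, rose by 0.44 ± 0.07 (adjusted p = 0.0052), whereas EXPA18 of the same list was at 0.04 ± 0.08. The small heat shock protein gene AT5G51440 fell by 0.98 ± 0.14 (adjusted p = 0.0033). In the joint fit of 14 arrays DFR, EXPA7 and AT5G51440 did not pass (adjusted p = 0.17, 0.37 and 0.089). None of the 4 measured genes induced by sugar starvation passed the threshold in roots (3 did adjusted over the list alone, and 1 passed as higher after median centring), nor did the 2 measured genes of sugar metabolism, with log2 changes from -0.22 to 0.30 in all 6. In all, 3 of the 37 list genes tested in roots passed.

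In gir inflorescences, the 3 tested late pollen genes fell 4-fold or more. Genes for pectin-modifying enzymes were 4 of the 12 largest falls of named genes, and glutaredoxin genes 2 of the 12 largest rises. Neither enzyme class was a fixed list, so how many of its genes did not change was not counted. The pectinesterase gene AT5G07420 fell from an intensity of 2298 ± 137 in Col-7 to 160 ± 66.1 in gir (SD, n = 4 each), a log2 change of -3.71 ± 0.21 (SE, adjusted p = 5.1e-07). AT59 (AT1G14420), a pectate lyase homologue, fell from 1274 ± 179 to 89.5 ± 32.6 (-3.53 ± 0.19, adjusted p = 3.2e-07). The polygalacturonase gene AT5G48140 (-3.32 ± 0.23) and the pectinesterase gene AT3G17060 (-3.29 ± 0.29) were also among the 12 largest falls. The glutaredoxin genes AT3G62960 and AT3G62930 rose by 2.45 ± 0.13 and 1.74 ± 0.15 (adjusted p = 3.1e-07 and 8.3e-06). The Col-7 intensities of AT3G62960 lay below the 40th percentile of their arrays, so the floor limits the size of its rise. MSRB9 (AT4G21850), a methionine sulfoxide reductase, rose from 131 ± 17.2 to 573 ± 83.3 (1.92 ± 0.12, adjusted p = 7.6e-07). QQS (AT3G30720), which affects leaf starch content, rose from 347 ± 41.2 to 1391 ± 308 (1.91 ± 0.14, adjusted p = 3.8e-06).

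All 3 tested genes of the late pollen list fell in gir inflorescences. ANX2 (AT5G28680), a receptor-like kinase of pollen tubes, fell from 381 ± 32.7 to 34.8 ± 19.0 (-2.80 ± 0.20, adjusted p = 2.4e-06). ACT12 (AT3G46520), a pollen actin, fell from 695 ± 33.2 to 137 ± 30.8 (-2.17 ± 0.12, adjusted p = 5.6e-07). MGH3 (AT1G19890), a histone H3 of the male germ line, fell from 413 ± 53.9 to 73.9 ± 33.0 (-2.19 ± 0.21, adjusted p = 3.1e-05). The gir intensities of ANX2 and MGH3, and of AT59, lay below the 40th percentile of their arrays, so the floor limits the size of those falls. Within the 4 same-numbered pairs of arrays their mean difference was -1.99, -2.09, -2.64 and -2.81. None of the 6 tested genes of the tapetum and pollen wall list passed the threshold, nor when adjusted over the list alone. For the list as a whole, the only fixed list large enough in inflorescences, camera gave a p of 0.67, which adjustment left unchanged. With other scalings 1 gene passed, AT1G75920 lower after quantile normalization (adjusted p = 0.049) and EMS1 higher after median centring (adjusted p = 0.039). AMS, a transcription factor of the tapetum, was at -0.09 ± 0.09, SPL at -0.07 ± 0.09 and the sugar transporter gene SWEET8 at -0.01 ± 0.08. EMS1, a receptor kinase needed to form the tapetum, was at 0.30 ± 0.11 (adjusted p = 0.069) and AT1G75920 at -0.47 ± 0.15 (adjusted p = 0.051).

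**Figure D2:**
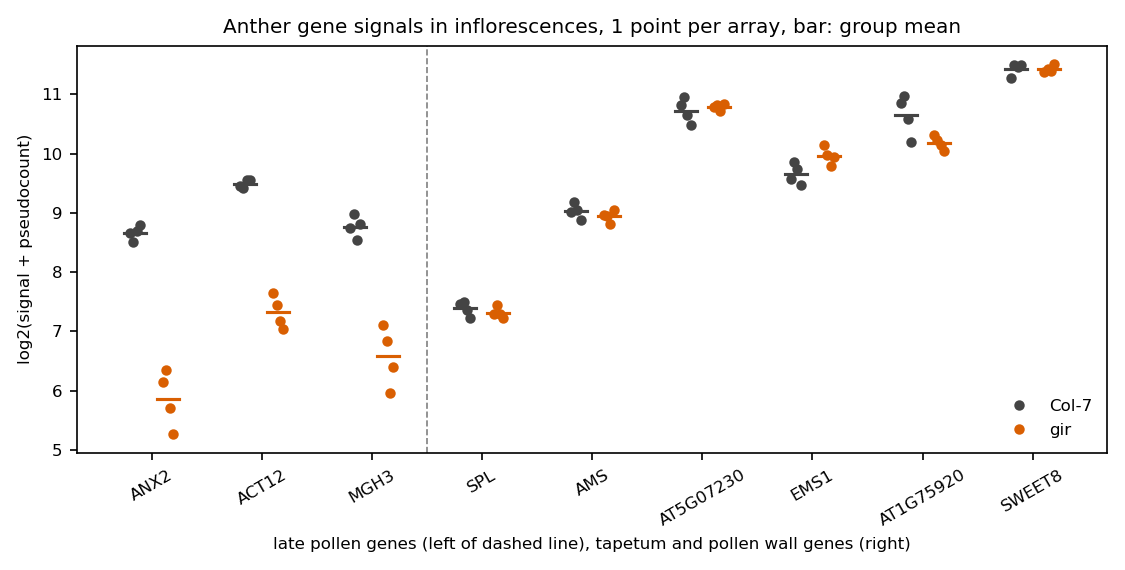
Log2(intensity + 26) of the 3 late pollen genes and the 6 tapetum and pollen wall genes tested in inflorescences (x axis), with 1 point per array (4 Col-7, 4 gir) and a bar at each group mean. ANX2, ACT12 and MGH3 lie lower in every gir array than in every Col-7 array, with log2 changes of -2.80, -2.17 and -2.19, while the 6 genes on the right did not pass the threshold with the scaling as deposited.

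In the other lists, COR47, a dehydrin of the abscisic acid response list, fell by 0.71 ± 0.08 (adjusted p = 0.0001) and the vacuolar invertase gene AT1G62660 fell by 0.68 ± 0.10 (adjusted p = 0.00057). ARR15, a cytokinin response regulator, rose by 0.55 ± 0.09 (adjusted p = 0.0017), whereas RR16, the other tested gene of that list, was at -0.28 ± 0.10 (adjusted p = 0.063, and 0.017 adjusted over the list alone). The Col-7 intensities of ARR15 lay below the 40th percentile of their arrays, so the floor limits the size of its rise. Of 3 measured photosynthesis genes, LHCB4.1 rose by 0.32 ± 0.08 (adjusted p = 0.018) and RCA by 0.26 ± 0.08 (adjusted p = 0.033), and neither passed after quantile normalization (adjusted p = 0.12 and 0.17). GRX480 (0.63 ± 0.18, adjusted p = 0.027) and APL3 (-0.63 ± 0.20, adjusted p = 0.048) were past the threshold too. Leaving out single arrays ended the LHCB4.1 call without Col-7 replicate 4 (adjusted p = 0.053, range 0.0084 to 0.053) and the RCA call without Col-7 replicates 2, 3 or 4 or gir replicates 2 or 4 (range 0.037 to 0.093). It ended the GRX480 call without Col-7 replicates 1 or 2 or gir replicates 2, 3 or 4 (range 0.018 to 0.069). The APL3 call ended without Col-7 replicates 1, 3 or 4 or gir replicates 2, 3 or 4 (range 0.0038 to 0.12), and also after quantile normalization (0.065), after median centring (0.053), with the smaller pseudocount (0.052) and without the filter (0.082), which ended the RCA call too (0.061). With replicates 1 and 2 alone LHCB4.1, RCA and APL3 did not pass (adjusted p = 0.35, 0.28 and 0.50). In all, 10 of the 42 list genes tested in inflorescences passed, 4 higher and 6 lower.

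Of 13970 probe sets tested in inflorescences, 3487 passed the threshold, 1744 higher and 1743 lower in gir. Large changes were mostly falls, since 652 probe sets fell and 147 rose at least 2-fold, and 330 fell and 11 rose at least 4-fold.  Median centring moved the balance to 2473 higher and 1577 lower. The 25S ribosomal RNA control signal followed the replicate number, at 345 in Col-7 and 359 in gir for replicate 1, 835 and 954 for replicate 2, 3424 and 2768 for replicate 3, and 6585 and 8660 for replicate 4. With replicates 1 and 2 alone, 583 were higher and 1086 lower, 1669 in all.

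The root plants were 21 days old and on plates with glucose, and the inflorescences came from 33-day-old plants on soil, so tissue, age, medium and glucose cannot be told apart in what follows. The signal of dap, a poly-A control probe set, was 0.874 to 21.4 on the root arrays and 235 to 400 on the inflorescence arrays. A difference in how the samples were processed may therefore be mixed with tissue as well. The genotype effect differed between the root and the inflorescence samples for 2168 of the 11911 probe sets tested in both, 1295 with a more positive and 873 with a more negative change in inflorescences. SP1L4 (AT5G15600), a SPIRAL1-like gene, rose by 0.55 ± 0.10 in gir roots and fell by 2.97 ± 0.11 in gir inflorescences, a difference of -3.52 ± 0.15 (SE, adjusted p = 3.6e-09). AT5G47000, a peroxidase gene, changed by 0.59 ± 0.14 and -3.02 ± 0.13, a difference of -3.61 ± 0.20 (adjusted p = 4.5e-08). AT3G56360 changed by 0.68 ± 0.09 and -1.65 ± 0.10. AT1G26450 went the other way, with -0.73 ± 0.09 in roots and 1.47 ± 0.08 in inflorescences. AT1G13970 fell by 2.97 ± 0.11 in inflorescences and was at 0.10 ± 0.08 in roots, a difference of -3.07 ± 0.15 (adjusted p = 1.5e-08). Without the filter 3283 probe sets passed, and with the stricter filter 1441.

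Among probe sets past the threshold in both tissues, opposite directions outnumbered equal ones. 122 were higher in gir roots and lower in gir inflorescences against 41.9 for independent lists (odds ratio 3.91, adjusted p = 3.7e-28), and 155 were lower in roots and higher in inflorescences against 80.5 (odds ratio 2.37, adjusted p = 1.9e-16). 93 were lower in both against 55.8 (odds ratio 1.86, adjusted p = 1e-06), and 48 were higher in both against 60.6 (odds ratio 0.76, adjusted p = 0.079). Fisher's test counts probe sets as independent units, which they are not, so these p-values do not measure the spread between samples. With median centring the 165 shared calls of equal direction lay near the 162 of independent lists, and with the stricter filter the 98 lay near 101. Across probe sets, which are not independent replicates, the root and inflorescence changes correlated at r = -0.0548 (Spearman's rho = -0.0847). AT1G56680 was higher in gir roots by 0.73 ± 0.07 and in gir inflorescences by 0.78 ± 0.12, and ARL (AT2G44080), an ARGOS-like regulator of organ size, by 0.63 ± 0.11 and 0.99 ± 0.15. For AT1G56680 the Col-7 inflorescence intensities lay below the 40th percentile of their arrays, so the floor limits the size of that rise. GH9B13 (AT4G02290), an endoglucanase gene, was at -0.46 ± 0.08 and -0.44 ± 0.08, and AT1G74010 at -0.63 ± 0.11 and -2.02 ± 0.10. Without the filter the root changes of GH9B13 and AT1G74010 did not pass (adjusted p = 0.058 and 0.051), and with inflorescence replicates 1 and 2 alone the inflorescence changes of AT1G56680 and GH9B13 did not (adjusted p = 0.076 and 0.083). Loci of opposite direction included AT5G05250, at 1.15 ± 0.12 in roots and -1.40 ± 0.13 in inflorescences, and AT5G20790, at 1.12 ± 0.13 and -1.35 ± 0.19.

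**Figure D3:**
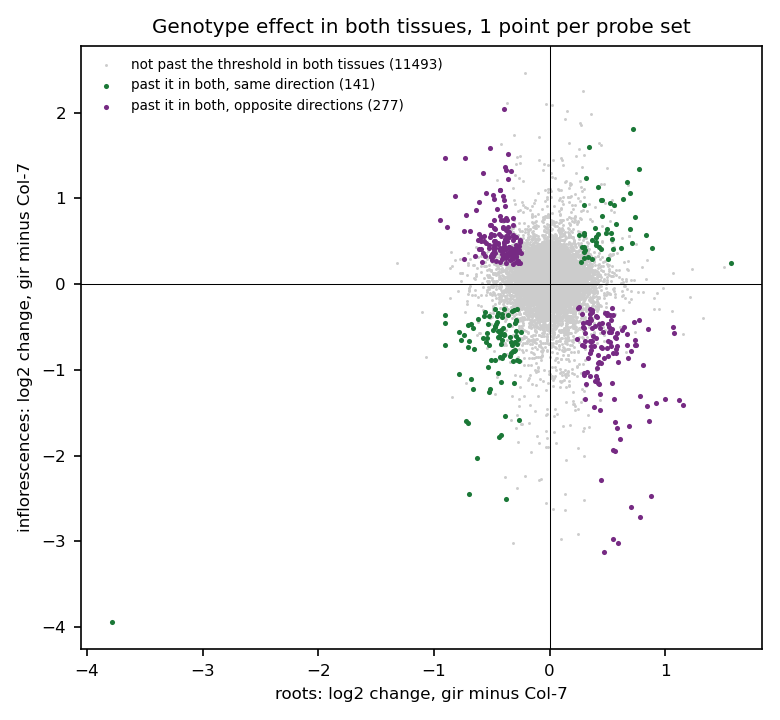
Log2 change of gir over Col-7 in roots (x axis) and inflorescences (y axis) for the 11911 probe sets tested in both, 1 point each. The 141 probe sets past the threshold in both in the same direction and the 277 in opposite directions are coloured, and the point at -3.79 and -3.94 is a probe set unnamed here.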

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

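Tests of the sample pairs by 25S ribosomal RNA, of co-movement among gir arrays, and of the actin ratio on opposite calls were chosen after the results they bear on had been seen.

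The genotype effect differed between the root and the inflorescence samples, which also differ in age, medium, glucose and the dap control signal, for 2168 probe sets by the interaction test. The named genes among them had been picked for large changes or a small p in that test, so their number carries no weight of its own. The differences (inflorescences minus roots, log2) among the genes with the largest root changes were -1.37 for AT1G22160, -2.55 for AT5G05250, -2.47 for AT5G20790, -1.64 for AT4G31330, 1.57 for AT3G44940 and 0.78 for EXPA15. For those with the largest inflorescence rises they were 2.48 for AT1G35210, 2.43 for AT4G18340, 1.79 for MSRB9 and 2.05 for AT3G62930. List members differed by -0.80 (COR47), 0.36 (LHCB4.1) and -0.54 (AT1G62660). AT1G73630 and AT1G74010, lower in both tissues, differed by -0.88 and -1.39. The genes of smallest p differed by -3.52 (SP1L4), -3.61 (AT5G47000), -2.34 (AT3G56360), 2.2 (AT1G26450) and -3.07 (AT1G13970). In 2 of 100 tests of the 4-array groups 1 array stood far from the others, and chance gives about 1 in 20. AT1G33170 was at 677 in Col-7 inflorescence replicate 1 against 587 to 590 in the other Col-7 arrays, and the actin 3' to 5' ratio was 2.22 in Col-7 inflorescence replicate 2 against 2.29 to 2.30.

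Chance regrouping was counted for each tissue. Of the 35 splits of the 8 inflorescence arrays 1, the real one, gave 3487 calls and the highest other gave 0, a share under 0.05. Of the 8 that part all same-numbered pairs, as the real one does, the others gave 0 too, but 8 splits alone are too few for a share under 0.05. In roots 1 of 10 splits gave 1636 calls and the highest other gave 0, but 10 splits are too few for a share under 0.05. Of 100 splits drawn for the interaction, 1 gave 2168 calls, and the highest other, 851, was the 1 drawn split that kept the inflorescence arrays grouped by genotype. The remaining 98 gave at most 41. These splits mixed the genotypes within a tissue, which removes the genotype effect itself as well as its difference between tissues. They therefore do not test the difference against an equal effect in both tissues. The flavonoid list in roots had a camera p of 0.0119 in the real split and of 0.0004 in another, so that 2 of 10 splits gave one as small, again with too few splits for a share under 0.05.

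Each inflorescence replicate number holds both genotypes, so the replicate batch that 25S ribosomal RNA follows cannot by itself make the fall of late pollen transcripts in gir. The mean difference of the 3 late pollen genes, from a list fixed beforehand, was -1.99 in the weakest of the 4 same-numbered pairs. All 3 were already known to be far lower in every gir array, so that test was bound to pass. The difference grew with the replicate number to -2.81, so an effect of the batch on its size is not excluded. The authors' scaling is argued against, as the mean change of the 3 genes was -2.34 under the rescaling that moved it most, against -2.38 as deposited. A smaller share of late-stage anthers or pollen in the gir samples may underlie the fall. Among the 4 gir arrays the 330 probe sets at least 4-fold lower, not shown to be pollen transcripts, moved together (mean pairwise correlation 0.44, 0.32 among Col-7 arrays, at most 0.043 in 200 random sets of like intensity), as did the 3 late pollen genes (0.784, -0.111 among Col-7 arrays), and the tapetum list, of earlier stages, had a median change of -0.04. But both sets stood in the order of the replicate number in gir, as 25S ribosomal RNA did, so the co-movement does not tell a smaller share from the replicate, from a shared regulator or from lower expression per cell, and the cause stays open.

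For the 277 probe sets called in opposite directions in the tissues, the authors' scaling is argued against, since they were still 1.98 times those of independent lists under the rescaling that lowered this most. RNA quality cannot be excluded: the actin 3' to 5' ratio was higher in gir roots than in Col-7 roots and, on average, lower in gir inflorescences than in Col-7 ones, but that of GAPDH did not reverse (0.943 in gir and 0.888 in Col-7 roots, 1.23 and 1.22 in inflorescences). For 59.9% of the 277, the slope on that ratio within the inflorescence groups had the sign of the root effect (16 of 576 reassignments of the ratios gave as many, exact one-sided p = 0.028), while within the root groups it was 52.3% (exact one-sided p = 0.19). Over all 11911 probe sets the slopes and effects correlated at 0.0029 and 0.053, the latter of the sign opposite to the one RNA quality would give, though this test dilutes the 277, so what RNA quality adds and a genotype effect that differs with tissue, plant age, medium or glucose cannot be told apart with 14 arrays.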

How the results depend on the processing

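The choice of leaving out inflorescence replicates 3 and 4 was made after seeing the data. The root count of 1636 became 616 without the filter, 707 in the joint fit of 14 arrays, 2549 at a threshold of 0.1 and 50 with 2-fold added, and ranged from 814 to 1216 without 1 array. Root replicate numbers were not taken as pairs, and gir replicate 2 correlated best with Col-7 replicate 1 and gir replicate 3 with Col-7 replicate 2. With the replicate number as a block 1281 passed in roots. The inflorescence count of 3487 became 799 with 2-fold added and 1669 with replicates 1 and 2 alone, and ranged from 2670 to 4102 without 1 array. The interaction count of 2168 became 3283 without the filter, 1441 with the 60th percentile filter and 363 with 2-fold added, and ranged from 1644 to 2619 without 1 array. With the replicate number as a block it was 3113. The block took the inflorescence count to 4865 and changed no call of a named gene or of a fixed list. In the main fit 141 shared calls had equal and 277 opposite directions, against 116 and 122 for independent lists. Without the filter they were 64 and 102, against 49.1 and 47.7. With inflorescence replicates 1 and 2 alone they were 81 and 150, against 44.3 and 43.6. The numbers for independent lists thus fell as well, and in both refits the shared calls stayed above them. The flavonoid list in roots had p = 0.22 after adjustment with an estimated correlation and 0.085 without the filter, ranged from 0.0033 to 0.071 without 1 array, and had fewer than 5 tested genes under the stricter filter. Why the counts moved was not tested. All other alternatives run left these counts within 1.5 times. No named gene changed direction under any alternative in which it was tested. The side of the threshold stayed the same in 652 of 688 refits of 39 root genes and 865 of 911 refits of 44 inflorescence genes. It did so in all 128 refits of the 5 interaction genes. A refit was counted only where the gene was tested, so refits in which it failed the filter are left out of these shares. Refits at the looser threshold of 0.1 are included, although they could not end a call, which raises the shares. Of the 26 and 46 calls that ended, 14 and 15 ended because 2-fold was required.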

Other observations

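The gene families and the single probe set described here were chosen after their values had been seen, and so were their tests.

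Endoglucanase genes of family GH9, which cut cell wall glucans, had only falls among their calls over all genes in both tissues. In gir roots 4 of 6 fell, and GH9C1 (0.25 ± 0.08, adjusted p = 0.089, but 0.018 as a rise adjusted over the list alone) and GH9B7 (-0.08 ± 0.07) did not pass. The falls were led by GH9B8 (-0.90 ± 0.08, SE) and GH9C2 (-0.70 ± 0.07), with a camera adjusted p of 0.009 (adjusted p = 0.27 with an estimated correlation). In gir inflorescences 7 of 9 fell and 2 did not pass, and the falls were led by GH9B11 (-3.08 ± 0.23) and GH9A4 (-2.69 ± 0.16), with a camera adjusted p of 0.00043 (adjusted p = 0.81 with an estimated correlation). The 3 late pollen genes fell in the same inflorescence arrays (mean -2.38), and whether the falls of GH9 genes there are apart from that was not tested. The family mean stayed negative in both tissues after quantile normalization (-0.39 and -0.99) and median centring (-0.34 and -0.97). Expansins and xyloglucan hydrolases went both ways in roots, where 4 of 20 rose, among them EXPA9 (0.71 ± 0.08) and EXPA8 (0.57 ± 0.07), and 6 fell, among them EXPA15, EXPB2 (-0.91 ± 0.14) and EXPB3 (-0.79 ± 0.07). EXPA8 fell in inflorescences (-1.94 ± 0.17). In roots the tau glutathione transferases (3 of 8 rose, adjusted p = 0.023, 0.28 as adjusted p with an estimated correlation), the cytochrome P450 family (3 of 8 rose, 0.00012 and 0.19) and the autophagy genes (3 of 8 rose, 0.010 and 0.58) had only rises among their calls. The autophagy calls were ATG8E (0.62 ± 0.09), ATG8H (0.41 ± 0.08) and ATG8F (0.34 ± 0.07). In inflorescences ATG8H fell (-1.10 ± 0.14).

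Among 11 measured SWEET sugar transporter genes in inflorescences 6 fell and 3 rose (camera adjusted p = 0.27). SWEET13 fell by 2.51 ± 0.17 and SWEET14 fell by 2.28 ± 0.21, whereas SWEET10 rose by 0.72 ± 0.08 and SWEET11 by 0.53 ± 0.08. The MADS-box genes AGL104 and AGL66, which act in pollen maturation, were at -2.16 ± 0.11 and -1.66 ± 0.13. The peptide genes RALFL25 and RALFL26 were at -2.99 ± 0.17 and -3.24 ± 0.30, and the expansin gene EXPB5 fell by 2.90 ± 0.13. Of the defensin-like genes, 1 rose and 3 fell of 4 in roots, too few for a list test, and 3 rose and 1 fell of 5 in inflorescences (camera adjusted p = 0.29, adjusted p = 0.82 with an estimated correlation). LCR68 was at -0.55 ± 0.08 in roots and 1.07 ± 0.08 in inflorescences, and PDF2.1 at -0.52 ± 0.09 and 1.59 ± 0.11.

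A probe set unnamed here had the smallest p in both tissues. Its intensity was 84.5 ± 9.78 in gir roots against 1496 ± 68.6 in Col-7 roots (SD, n = 3), a log2 change of -3.79 (adjusted p = 1.7e-07), and 52.1 ± 8.25 in gir inflorescences against 1165 ± 32.8 in Col-7 ones (n = 4), a change of -3.94 (adjusted p = 7.8e-09). In roots it was the 1 probe set at least 8-fold lower. A hypothesis is that it may report the transcript of the mutated gene. The difference between the tissues was -0.15 ± 0.12 (SE, adjusted p = 0.42), but all 7 gir arrays lay below their own 40th percentile (111 to 117 in roots, 126 to 130 in inflorescences), where the floor limits the size of both falls. The difference therefore does not test the hypothesis, which stays open, as do a direct target of GIR1 and a second difference between the lines.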
